A study of Mus musculus with 3 samples.

How the data were processed

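Dentate gyri were dissected from adult male mice, poly(A) RNA was selected, fragmented, reverse transcribed with random primers and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The 3 libraries form 1 wild-type group by their titles. Read alignment and quantification used TopHat and Cufflinks with the builds mm9 and NCBIM37, per the submitters' processing notes; versions, read length and strand setting are not given in the sources used here. The protocol describes no step that marks the strand, so reads of overlapping antisense genes cannot be told apart.

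The values are FPKM, fragment counts scaled by transcript length and by the number of mapped fragments, as deposited by the authors in a table for the whole series whose column header names that unit. Its 37681 rows each pair an Ensembl gene with 1 listed transcript and its mm9 span, and 36469 of them hold a value. The table holds 1 column of values, so the group value is the authors' own, whether from pooled reads or from an average is not given in the sources used here, and no standard deviation or n can be attached. Values per library and read counts were not analysed here. The depth behind each value is therefore unknown, and no counting interval or detection limit is given. The other 1212 rows hold no value and were left out. The value may belong to the gene or to the listed transcript; the closing section gives the checks made. Of 49 genes in the gene pairs, 46 had their listed transcript in GENCODE M21. It was a noncoding form for 6 of them, namely Dnmt3a, Dnmt3l, Uhrf2, Hdac3, Gabra2 and Gria3, and a coding form under 0.5 of the longest for 6, namely Gad1, Sin3a, Sin3b, Gria2, Grin2a and Grin2b. The ratios of these genes carry this limit, as do the values of Vtn, Actn3 and Prlr, whose listed transcripts are retained-intron forms. List medians can carry it too. The medians of the astrocyte, pan-neuronal and housekeeping lists rest in part on Gfap, Mtap2 and Gapdh, named after their values were seen. Their listed transcripts were 356, 546 and 565 nt long, those of Gfap and Gapdh being noncoding forms. Cufflinks can write 0 where an estimate fails, so such a gene is said to be listed at 0.

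Rows that share a gene name (311 names) were summed, and the place was taken from the row with the highest value. Start positions were converted to 1-based numbers. Gene types, transcript types and transcript lengths were taken from GENCODE M21 by Ensembl identifier only, since its coordinates are of another build. Gene identifiers of 32661 rows (86.7%) were found there. All 295 names of the preset lists were found, 291 by symbol and 4 by identifier. The 7 names of the red blood cell list gave 5 genes, because some of them name the same gene.

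Before the data were examined, 29 gene lists, 33 gene pairs, 19 pairs of lists, the alternatives and the rule for named genes were fixed. The planned limma tests of within-library ratios, the exact sign-flip tests, the replicate correlations and the ranking of lists by variation need values per library and were not run; the design with 3 libraries would have allowed a smallest two-sided sign-flip p of 0.25. In their place, gene pairs are given as ratios of the deposited values and list pairs as differences of list medians on the log2(FPKM + 0.1) scale, which understates differences that involve low genes. No p-value is given anywhere. Each list median was placed among 10000 random lists of the same size drawn from names at 0.1 FPKM or more together with the list's own members, not matched on level, with the highest and lowest 2.5% as limits. The rule named all members of the 4 DNA methylation lists, the 2 highest and the lowest member of every other list, both genes of each pair and the 20 highest names. It also named the 10 most variable genes, which could not be determined. Genes named outside the rule are marked, and some genes that it names are not reported here.

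The random-list step was tested on simulated data: of 50 unshifted lists of 12 drawn from 16367 names, 2 were called high and 3 low, and of 50 such lists raised by 3 on the log2 scale, 48 were called high. Of 50 lists raised by 1, 14 were called high. Lists of 6, a size near that of the smallest lists, were called less often, 38 of 50 at 3 and 10 of 50 at 1. Alternatives changed the pseudocount (1 and 0.01), the minimum FPKM, the list summary, the handling of shared names and, chosen after the data were seen, the background, the nuclear copies of mitochondrial genes, the members listed at 0 and the restriction to protein-coding genes. Sequence matches used blastn 2.17.0 on GENCODE M21 transcripts, taken by gene name. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.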

Results

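Messenger RNA was sequenced from micro-dissected dentate gyrus, the hippocampal subregion built around the granule cell layer, of adult male C57BL/6 mice aged 8 to 10 weeks. The series held 1 group of 3 wild-type libraries, described as biological replicates, and no second condition, so the comparisons below are between genes and gene groups within this tissue. The analysed table carried 1 FPKM value per gene for the whole group. There was therefore no replicate error for any value, no test against replicate spread was possible, and the sequencing depth behind the values was unknown. A value was present for 36469 of 37681 gene entries, which bore 33101 different gene names. Of these names, 13092 reached 1 FPKM, 6978 reached 10 FPKM, 690 reached 100 FPKM and 13381 were listed at 0. The names at 1 FPKM or more included 992 of 3735 processed pseudogenes, and whether their reads came from parent genes was not tested. Among 20124 protein-coding names, 11341 (56.4%) reached 1 FPKM, and the median of those was 11.5 FPKM.

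The most abundant transcripts came from the mitochondrial chromosome, which made up 18.4% of the summed FPKM. mt-Co3, a cytochrome c oxidase subunit, was highest at 16089 FPKM, followed by the ATP synthase subunit mt-Atp8 at 14404 FPKM, mt-Co2 at 14250 FPKM, mt-Co1 at 8938 FPKM and mt-Atp6 at 7951 FPKM. The other mitochondrial transcripts among the 20 highest names were mt-Nd3 at 3954 FPKM, mt-Nd4 at 3689 FPKM, mt-Cytb at 2642 FPKM, mt-Nd4l at 2482 FPKM, mt-Nd1 at 2382 FPKM, mt-Nd2 at 1737 FPKM and mt-Nd6 at 1101 FPKM, together with the ribosomal RNAs mt-Rnr2 at 1995 FPKM and mt-Rnr1 at 1661 FPKM. All 13 mitochondrially encoded protein genes exceeded 1000 FPKM, down to mt-Nd5 at 1079 FPKM. The entries of mt-Atp8 (7766 to 7969) and mt-Atp6 (7927 to 8607) overlap in position, as do those of mt-Nd4l and mt-Nd4. The division of reads between such entries is uncertain, so differences between their values may not be differences in abundance. The nuclear protein-coding genes among the 20 highest names were Apoe, the main apolipoprotein of brain, at 1493 FPKM, Tmsb4x, which encodes the actin-sequestering thymosin beta 4, at 1246 FPKM, Camk2a, the alpha subunit of the postsynaptic kinase CaMKII, at 1205 FPKM, and the translation elongation factor Eef1a1 at 1192 FPKM. The other 2 places were held by predicted genes on chromosome 1, Gm10925 at 6726 FPKM and Gm10222 at 2487 FPKM. Their GENCODE M21 sequences, taken by gene name, were identical to mitochondrial genes. The 100 highest names carried 31.1% of the summed FPKM, and 17.5% when the mitochondrially encoded protein genes were left out of both parts.

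The study as a whole concerned methylation outside CpG sites in adult brain, and the first question was which writers, readers and removers of DNA methylation were transcribed in this tissue. Among the writers, the maintenance methyltransferase gene Dnmt1 stood at 9.44 FPKM and the de novo methyltransferase gene Dnmt3a at 7.99 FPKM, a ratio of Dnmt1 to Dnmt3a of 1.18. The other de novo enzyme gene, Dnmt3b, and the catalytically inactive cofactor Dnmt3l were both listed at 0. Uhrf2 reached 24.3 FPKM, whereas Uhrf1, the partner of Dnmt1 at replicating DNA, was at 0.0227 FPKM, and Trdmt1, best known as a tRNA methyltransferase, was at 1.77 FPKM. In the mm9 coordinates of the table, the listed transcript of Dnmt3a spanned 3806007 to 3838814 on chromosome 12, that of Dnmt1 spanned 20711650 to 20757317 on chromosome 9, and that of Dnmt3b spanned 153475186 to 153513466 on chromosome 2. The listed transcripts of Dnmt3a, Uhrf2 and the deacetylase gene Hdac3 are annotated as retained-intron forms in GENCODE M21.

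All 10 genes of the preset methyl-DNA reader list were at 1 FPKM or more, with a list median of 14.2 FPKM. Whether the product of each member binds methylated DNA was not examined. Mbd3, whose protein belongs to the NuRD complex, was the highest member at 69.3 FPKM, and its listed transcript spanned 79855284 to 79862295 on chromosome 10. Mbd2 was at 23.4 FPKM, Mbd1 at 11.7 FPKM and the DNA glycosylase gene Mbd4 was lowest at 2.42 FPKM. Mbd5 was at 20.9 FPKM, Mbd6 at 5.74 FPKM, and the zinc finger readers Zbtb4, Zbtb38 and Zbtb33 were at 17.7, 8.89 and 7.12 FPKM. The reader median lay above the writer median by 2.91 on the log2(FPKM + 0.1) scale, but by 0.80 once members listed at 0 were left out. The writer median of 1.77 FPKM was the value of Trdmt1, the gene best known for tRNA methylation. Uhrf2, Dnmt1 and Dnmt3a lay above it, and Uhrf1, Dnmt3b and Dnmt3l below.

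Of 12 genes linked to removal of DNA methylation, 9 reached 1 FPKM, and the list median was 2.78 FPKM, below the reader median by 2.29 on the log2 scale. Among the dioxygenase genes that oxidise 5-methylcytosine, Tet3 was highest at 5.62 FPKM, Tet2 was at 2.76 FPKM and Tet1 at 0.801 FPKM, so that Tet3 exceeded Tet2 by 2.04-fold and Tet1 by 7.02-fold, and Tet2 exceeded Tet1 by 3.45-fold, as ratios of the values without a pseudocount. The glycosylase genes Tdg and Smug1 were at 11.2 and 4.03 FPKM. Gadd45g was at 16.4 FPKM, 4.15 times Gadd45b at 3.95 FPKM, and Gadd45a was at 2.79 FPKM. Among cytidine deaminase genes, Apobec3 was at 1.23 FPKM, Apobec1 at 1.08 FPKM and Apobec2 at 0.0195 FPKM.

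The 12 genes of transcriptional corepressors and their partners were all at 5 FPKM or more, with a median of 25.1 FPKM. This median exceeded that of 98.6% of 10000 random lists of the same size drawn from genes at 0.1 FPKM or more, and 98.0% of lists drawn from protein-coding genes. With a background of genes at 0.5 FPKM or more, the percentile was 96.6, outside the highest 2.5%. The nuclear corepressor gene Ncor1 was highest at 63.0 FPKM. Among histone deacetylase genes, Hdac2 was at 57.9 FPKM and Hdac3 at 37.0 FPKM, 4.08 and 2.61 times Hdac1 at 14.2 FPKM. Sin3b was at 35.1 FPKM, 3.81 times Sin3a at 9.22 FPKM, with short listed transcripts of 1024 and 364 nt. The proto-oncogene Ski was at 57.7 FPKM, the chromatin remodeller gene Atrx at 15.1 FPKM, Gps2 at 14.8 FPKM, Tbl1xr1 at 9.48 FPKM and Tbl1x at 5.76 FPKM.

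**Figure D1:**
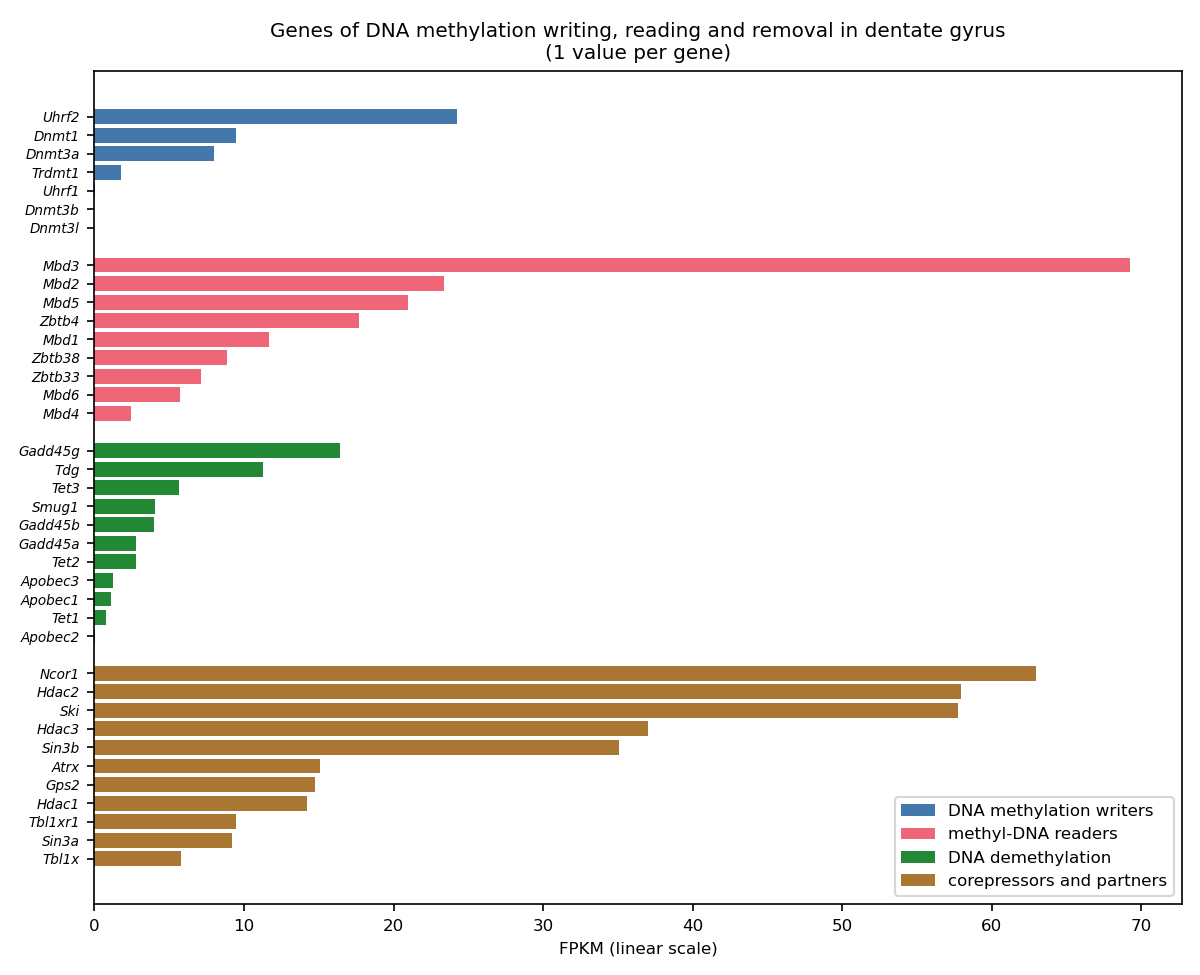
FPKM (horizontal axis, linear, 1 value per gene without error bars) of the preset lists of writers, readers, demethylation genes, and corepressors and partners. Genes are ordered by value within each group, with some list members not drawn. Mbd3 at 69.3 FPKM and Ncor1 at 63.0 FPKM are the longest bars, and Dnmt3b and Dnmt3l, listed at 0, have none.

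The next question was which cell type markers were transcribed in the dissected tissue. Pan-neuronal and excitatory genes were abundant: all 12 exceeded 10 FPKM, the median was 186 FPKM, and no random list reached it. Camk2a at 1205 FPKM and the calmodulin-binding postsynaptic gene Nrgn at 617 FPKM led the list, and the neurofilament gene Nefm was lowest at 56.7 FPKM. Camk2a exceeded Camk2b, at 635 FPKM, by 1.90-fold. Slc17a7, which encodes the vesicular glutamate transporter of cortical and hippocampal neurons, was at 318 FPKM, 464 times its relative Slc17a6 at 0.686 FPKM.

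Astrocyte genes lay close below the neuronal list, by 0.48 between medians on the log2 scale and by 1.37 between list means. Their median was 140 FPKM, led by the glycolytic enzyme gene Aldoc at 511 FPKM and the glutamine synthetase gene Glul at 502 FPKM, with the transcription factor gene Sox9 lowest at 0.925 FPKM. All 10 oligodendrocyte genes reached 1 FPKM, with a median of 27.9 FPKM, and the myelin gene Mbp was at 261 FPKM against 5.94 FPKM for Olig2. The precursor list was lower, with a median of 4.65 FPKM, Pdgfra at 10.1 FPKM, Gpr17 at 9.23 FPKM and Neu4 at 0.392 FPKM. All 10 microglial genes reached 1 FPKM, with a median of 23.1 FPKM, the complement gene C1qb at 38.9 FPKM and Aif1 at 3.51 FPKM. Endothelial and pericyte genes had a median of 2.84 FPKM, with Vtn at 16.8 FPKM and Rgs5 at 8.22 FPKM, and Pecam1 was listed at 0. The pan-neuronal median exceeded the medians of the oligodendrocyte, precursor, microglial and endothelial lists by 2.75, 5.28, 3.01 and 6.03 on the log2 scale. Such gaps between lists, the astrocyte list included, depend on which genes each list holds. They do not measure the share of each cell type in the tissue. GABAergic interneuron genes had a median of 10.7 FPKM, 4.10 on the log2 scale below the pan-neuronal list, which is not limited to excitatory neurons. Their highest members were the somatostatin gene Sst at 109 FPKM and the glutamate decarboxylase gene Gad1 at 87.1 FPKM, 8.25 times its partner Gad2 at 10.6 FPKM, and the lowest was Lhx6 at 0.444 FPKM. The listed transcript of Gad1 was a short form of 398 nt, against 5744 nt for Gad2.

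Markers of tissues outside the dissection were low. Choroid plexus and ependymal genes had a median of 0.0484 FPKM, with Kl at 6.06 FPKM, the transthyretin gene Ttr at 2.13 FPKM, and Prlr and Folr1 listed at 0. Markers of other organs had a median of 0.0308 FPKM. The pan-neuronal median exceeded the choroid plexus and other organ medians by 10.30 and 10.46 on the log2 scale, and by 7.47 and 7.49 with a pseudocount of 1 FPKM. The highest of the other organ markers were Sftpc at 2.19 FPKM and Actn3 at 0.689 FPKM, and Alb, Ins2 and Umod were listed at 0. Of 8 pluripotency genes, 7 were listed at 0, and Tdgf1 was at 0.288 FPKM. Globin genes were present, led by Hba-a2 at 73.2 FPKM and Hbb-b1 at 64.0 FPKM. Alas2, the erythroid enzyme of heme synthesis, was at 0.213 FPKM. The alpha globin genes are close paralogs of each other, as are the beta globin genes, so the division of reads within each group is uncertain.

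**Figure D2:**
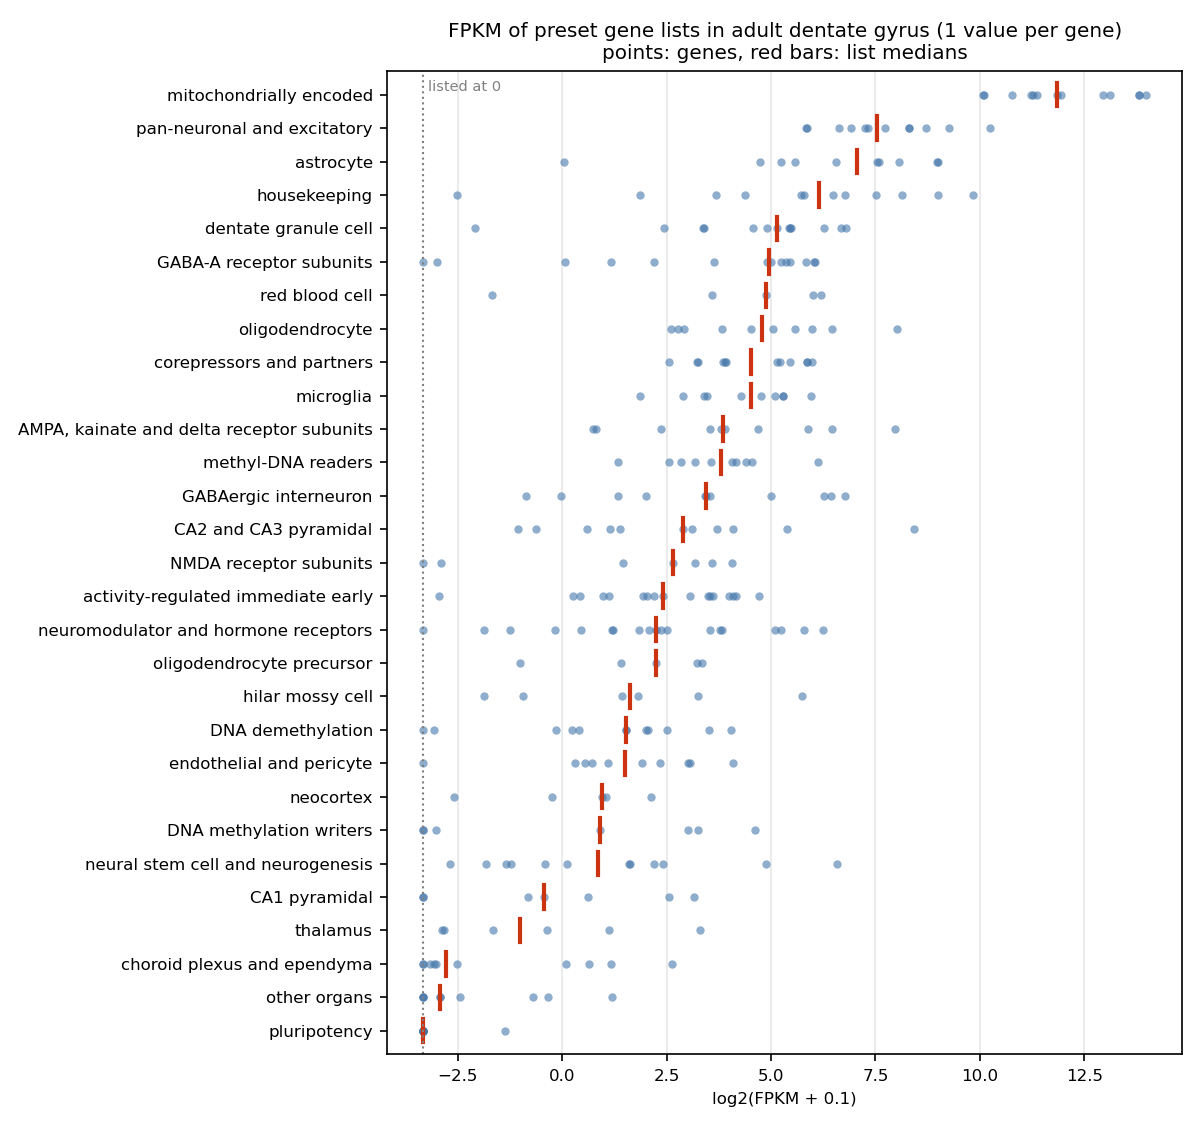
Level of each preset gene list on a log2(FPKM + 0.1) axis, with a point per gene, a red bar for the list median and a dotted line for genes listed at 0. Pan-neuronal and astrocyte lists have the highest medians among cell type lists, at 186 and 140 FPKM, and the choroid plexus, other organ and pluripotency lists lie near the dotted line.

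Within the hippocampal formation, the list of dentate granule cell genes had the highest median. Of 13 such genes, 11 exceeded 10 FPKM, and the median of 35.5 FPKM exceeded that of 99.9% of random lists. The complement-related synaptic genes C1ql2 and C1ql3 were at 111 and 102 FPKM, the calcium-binding protein gene Calb1 was at 77.4 FPKM, and Dock10 was lowest at 0.137 FPKM. Prox1, the transcription factor that specifies granule cells, was at 44.8 FPKM (named after its value was seen). CA1 pyramidal genes had a median of 0.637 FPKM, with Wfs1 at 8.81 FPKM, Fibcd1 at 5.83 FPKM, and Pou3f1 listed at 0. The granule cell median exceeded the CA1 median by 5.59 on the log2 scale, and by 4.54 with members listed at 0 left out. It exceeded the joint CA2 and CA3 list by 2.25, the hilar mossy cell list by 3.53 and the interneuron list by 1.72, and by 2.88 and 1.06 for the last 2 lists when list means replaced medians. As above, these gaps depend on the genes chosen for each list and do not measure cell numbers.

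The CA2 and CA3 list spanned a wide range around a median of 7.37 FPKM, from Pcp4 at 341 FPKM and Rgs14 at 41.5 FPKM to Map3k15 at 0.378 FPKM. Pcp4 exceeded every member of the granule cell list, and which cells carried it was not tested. Among hilar mossy cell genes, the calretinin gene Calb2 was at 53.0 FPKM, Ajap1 at 9.38 FPKM and the dopamine receptor gene Drd2 at 0.173 FPKM. Calb1 exceeded Calb2 by 1.46-fold. Thalamic genes had a median of 0.445 FPKM, with Ntng1 at 9.69 FPKM, Zic1 at 2.06 FPKM and Gbx2 at 0.0358 FPKM, and neocortical genes had a median of 1.84 FPKM, with Fezf2 at 4.29 FPKM, Cux2 at 1.98 FPKM and Tshz2 at 0.0659 FPKM. The granule cell median exceeded these lists by 6.17 and 4.19 on the log2 scale, the first of which was 4.68 with a pseudocount of 1 FPKM. Stem cell and neurogenesis genes, a list with markers of progenitors and of immature neurons, had a median of 1.96 FPKM. This median lay below the granule cell median by 4.29 on the log2 scale, or by 3.46 between list means. Hopx was highest at 95.9 FPKM, followed by Neurod1 at 29.4 FPKM. Which cells carried these 2 transcripts was not tested. Of the 12 genes, 6 reached 1 FPKM. Dcx, a marker of immature neurons, was lowest at 0.0557 FPKM. With the depth unknown, this single value says little about how many immature neurons were present.

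Transmitter receptor genes differed widely in level within each family. Among glutamate receptor genes of the AMPA type, Gria1 was highest at 249 FPKM, 2.84 times Gria2 at 87.8 FPKM and 49.3 times Gria4 at 5.05 FPKM, and Gria2 exceeded Gria3 by 3.41-fold. For the NMDA receptor, Grin2a was at 16.7 FPKM, 1.87 times Grin2b at 8.92 FPKM, and Grin2b exceeded Grin2d by 3.40-fold. Grin2c was at 11.9 FPKM. Grin1, the subunit shared by NMDA receptors, was listed at 0. Of 14 GABA-A receptor genes, 9 exceeded 10 FPKM, and the median of 31.0 FPKM exceeded that of 99.8% of random lists. Gabra2 and Gabra4 were at 40.7 and 37.8 FPKM, Gabrd, whose subunit forms extrasynaptic receptors, was at 32.1 FPKM, and Gabra6 was listed at 0. The GABA-A median exceeded that of the AMPA, kainate and delta list, which differed from it by -1.10 on the log2 scale, but the difference of list means was 0.83 in the opposite direction.

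Receptors for hormones and neurotrophins also differed in level. The mineralocorticoid receptor gene Nr3c2 was at 37.9 FPKM, 2.77 times the glucocorticoid receptor gene Nr3c1 at 13.7 FPKM. Ntrk2, the receptor gene for brain-derived neurotrophic factor, was at 75.7 FPKM, 2.20 times Ntrk3, and the muscarinic receptor gene Chrm1 was at 54.9 FPKM. Of 17 activity-regulated immediate early genes, 16 reached 1 FPKM, with a median of 5.22 FPKM. Egr3 was highest at 26.2 FPKM, Bdnf was at 17.7 FPKM and Egr2 lowest at 0.0303 FPKM. Housekeeping genes had a median of 72.5 FPKM, with Actb highest at 919 FPKM. Gusb, a lysosomal enzyme gene often used as a reference, was at 0.0752 FPKM. Whether this value reflects a low level or a poor estimate was not tested.

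Counted over all 29 lists, 9 had a median within the highest 2.5% of random lists and 5 within the lowest 2.5%. The high lists were the pan-neuronal, astrocyte, housekeeping, mitochondrial, granule cell, GABA-A receptor, oligodendrocyte, corepressor and microglial lists. The microglial list left this range against protein-coding genes only, at a percentile of 96.5, against genes at 0.5 FPKM or more, at 95.4, and marginally with the highest entry kept for shared names. The corepressor list left it against genes at 0.5 FPKM or more, at 96.6, and the GABA-A receptor list with list means, at 80.1. The low lists were those of CA1, thalamus, choroid plexus, other organs and pluripotency. With a background from 0.01 FPKM the CA1 and thalamus lists left the low range, at percentiles of 10.6 and 6.03, and without members listed at 0 the CA1 and pluripotency lists did, at 9.30 and 7.87. The medians of the choroid plexus, other organ and pluripotency lists lay under the 0.1 FPKM minimum of the random background, which by itself gave them a percentile of 0. With a background from 0.01 FPKM, the choroid plexus and other organ lists stood at 0.02 and 0.04. Other lists entered the low range against genes at 0.5 FPKM or more and with list means. These were the writers (8.75 as reported, then 1.04 and 0.74), the demethylation genes (9.01, then 1.29 and 1.05) and the neurogenesis genes (2.99, then 0.10 and 1.17, and 0.85 against protein-coding genes). The endothelial list entered it at 1.67 in the first of these settings and the neocortical list at 1.87 in the second. These percentiles describe a single set of values, and genes are not replicates.

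Chromosome class and gene span were compared with level. X-linked genes at 1 FPKM or more had a median that differed from that of autosomal genes by -0.20 on the log2 scale (531 and 12542 genes, log2 medians 3.30 and 3.49). Among protein-coding genes the medians were 11.2 FPKM for 378 X-linked and 11.5 FPKM for 10946 autosomal genes. Across the 13092 names at 1 FPKM or more, the span of the listed transcript was barely related to level (Spearman rho -0.037, Pearson r -0.066), and the sign of this correlation changed at a lower minimum (Spearman rho 0.067 at 0.1 FPKM), though not among protein-coding genes (-0.00798). Detection differed more with span. Of protein-coding genes with a span under 5 kb, 34.1% reached 1 FPKM, against 53.3% of those spanning 5 to 10 kb, 63.8% of those spanning 20 to 50 kb and 74.0% of 831 genes spanning over 200 kb. Their median once above 1 FPKM stayed between 10.4 and 12.9 FPKM in all 7 span classes. The highest genes spanning over 200 kb, named after their values were seen, were the calcium sensor gene Ncald at 336 FPKM, Nell2 at 295 FPKM and Gria1 at 249 FPKM.

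**Figure D3:**
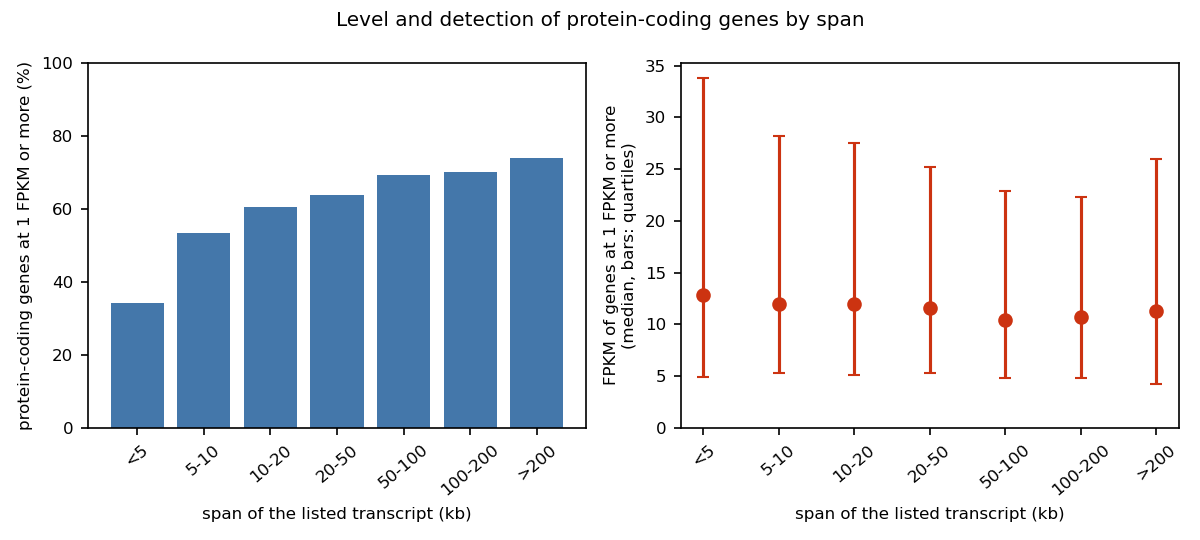
Left, percent of protein-coding genes at 1 FPKM or more in 7 classes of listed transcript span in kb. Right, median FPKM of the genes at 1 FPKM or more, with bars from the lower to the upper quartile of genes, not replicate error; detection rises from 34.1% to 74.0% while the medians stay between 10.4 and 12.9 FPKM.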

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

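The restriction to protein-coding genes, at either minimum, and the removal of nuclear copies or of members listed at 0 were chosen after seeing the data. With no replicate spread or depth to set against, a value was taken to have moved when it changed by over 1.5 times. No paired analysis was possible because the series has 1 group and 1 column of values; for the same reason no replicate could be left out, no library could be rescaled and no average over libraries could be formed. In 24 of 33 gene pairs the first gene was higher, which a pseudocount cannot change, and keeping the highest entry for shared names left all 33 values as they were. The log2 ratio of 8 pairs moved with a pseudocount of 1 FPKM and of 5 pairs with 0.01 FPKM. Tet3 to Tet1 fell from 2.67 to 1.88 with a pseudocount of 1 FPKM, Tet2 to Tet1 from 1.67 to 1.06 and Slc17a7 to Slc17a6 from 8.66 to 7.56. Of 19 list pairs, 18 had the first list higher, and 19 with list means, where the AMPA, kainate and delta list against the GABA-A list turned to 0.83. The number of names at 1 FPKM or more moved by less than 1.5 times, from 13092 to 16367 at a minimum of 0.1 FPKM, to 9521 at 5 FPKM and to 11341 for protein-coding names. The share of the 100 highest names fell from 31.1% to 17.5% without mitochondrially encoded genes, and to 15.0% without the mitochondrial chromosome and its 2 nuclear copies (14.9% without a further copy), because these genes hold the highest values. Lists within the lowest 2.5% numbered 5, but 3 with a background minimum of 0.01 FPKM, 9 with 0.5 FPKM, 9 with list means and 3 without members listed at 0; a higher minimum raises the background by construction. The difference of X-linked from autosomal genes was -0.57 at a minimum of 0.1 FPKM, -0.089 at 5 FPKM and -0.047 for protein-coding genes, against -0.20. Protein-coding genes were 378 of the 531 X-linked and 10946 of the 12542 autosomal names at 1 FPKM or more. The gap of -0.20 was thus mostly absent among coding genes, so it does not show a lower level of X-linked coding genes. Its cause was not tested. The correlation of span with level turned to 0.067 (Spearman) and 0.060 (Pearson) at a minimum of 0.1 FPKM, and was -0.114 (Spearman) at 5 FPKM and -0.061 for protein-coding genes. Among protein-coding genes at a minimum of 0.1 FPKM it was -0.00798, so that the turn of sign was absent there. Unknown depth limits what can be said of values far below 1 FPKM.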

Other observations

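Families outside the preset lists, chosen after the data were seen, showed sharp contrasts. None of 1097 olfactory receptor genes and none of 315 vomeronasal receptor genes reached 1 FPKM, and 1065 and 303 of them were listed at 0. Of 39 Hox genes, 38 were listed at 0, and Hoxb4 was at 0.0087 FPKM. Among voltage-gated channel genes, the sodium channel gene Scn8a was at 35.2 FPKM, and Cacna1h, which encodes a low-threshold calcium channel, led the calcium channel subunits at 42.1 FPKM. Of 32 interleukin genes matched by symbol, 16 were listed at 0, and Il16 was highest at 22.3 FPKM, followed by Il18 at 15.3 FPKM and Il33 at 11.1 FPKM. Atp6v0c led the vacuolar ATPase genes at 444 FPKM.

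The families above and the tests on zeros and on span below were chosen only after the results were seen, and the test on nuclear copies before. 2 of these tests replaced others. A first test on zeros took 3 or more members of the complexes at 0 as evidence against reading 0 as true absence. The 4 members found met it, but all were tissue-restricted relatives, named below, for which a 0 may be true absence. That outcome therefore decides nothing. A first test on span was set on longer genes having higher values, which was absent among names at 1 FPKM or more (Spearman rho -0.037, and -0.061 for protein-coding names) and weak among names at 0.1 FPKM or more (0.067, and -0.00798 for protein-coding names). Over all protein-coding names, those at or near 0 included, the median rose from 0.0121 FPKM for spans under 5 kb to 5.64 FPKM for spans over 200 kb. The bounds of both replacements were set with the outcome known or roughly known. Apart from the chemoreceptor families below, no biological explanation was tested for any pattern, because the design has 1 group.

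Gm10925 (chromosome 1, 24620814 to 24621627) and Gm10222 (chromosome 1, 24619243 to 24619539) were the highest nuclear names. Their GENCODE M21 sequences matched mt-Atp6 with mt-Atp8, and mt-Nd4l, at 100% identity over 100% of their length. The deposited identifier of Gm10925 was not found in GENCODE M21. Its matched sequence, of 678 nt, was taken by gene name and may differ from the entry that was quantified. Gm10222 stood at 1.00 times the value of mt-Nd4l, and Gm10925 at 0.846 times that of mt-Atp6, whereas Gm13341 (659.8 FPKM, chromosome 2), which matched mt-Co2 at 95.9% identity over 100% of its length, stood at 0.0463 times mt-Co2. Reads of mitochondrial origin divided between identical copies are a candidate explanation. Whether such reads were split or counted at both places, and transcription of the chromosome 1 copies themselves, stay open.

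Grin1 was listed at 0 although Grin2a and Grin2b, whose products assemble with it, were not, and Rpn2, Fkbp1a, Elavl4 and Rbfox2, named after their values were seen, were also listed at 0. Of 180 members of 8 complexes that every cell uses, 4 (2.22%) were listed at 0, namely the tissue-restricted relatives Rpl10l, Rpl39l, Atp6v1b1 and Atp6v1e2, which leaves open how frequent failed estimates written as 0 are, since Rpn2 lies outside these complexes and no bound was set before the count was known. Whether the table's value is that of the listed transcript stays open. Among protein-coding genes with over 5 transcripts, 6.09% of 673 genes with a noncoding listed transcript were listed at 0. The share was 6.88% of 5187 with a coding one (ratio 0.885), and the medians were 8.77 and 9.48 FPKM. Coding listed transcripts shorter than 0.5 of the longest form were at 0 in 9.62% of 717 genes, against 6.44% of 4470 others (ratio 1.49). Here the medians were 9.12 and 9.67 FPKM. The medians of these classes lay close together, but the values of single genes may still be those of the listed transcript. Failure of single genes such as Grin1 may also remain. A 0 in this table is therefore weak evidence of absence for a single gene, Dnmt3b and Pecam1 included.

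Fewer protein-coding genes with a span under 5 kb reached 1 FPKM (34.1%) than of those spanning 5 to 10 kb (53.3%). Chemoreceptor families at the short end were tested as the whole cause, and leaving them out closed 41.2% of the gap (42.8% of 3665 against 54.1% of 2912 genes), so they may account for a part only. Other short, tissue-restricted families were not tested.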
